A study of Homo sapiens with 9 samples.

How the data were processed

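RNA of BL41 cells labelled for 60 min with 100 µM 4sU was measured as 3 fractions, nt-RNA, tc-RNA and p-RNA, on 3 arrays each. Per the labels' protocols, RNA was extracted with Trizol and prepared with the one-cycle biotin labelling of Affymetrix. The deposited values are linear intensities per probe set, and GCRMA is named in the submitters' processing notes, with its version and the set of arrays normalized together not given in the sources used here. Deposited intensities of nt-RNA replicate 1 have 2 decimals and those of the other 8 arrays are whole numbers. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

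Of 54675 probe sets, 41097 named 1 gene in the platform annotation, 1801 named several and 11777 were not listed there. Symbols were updated through gene identifiers of the RefSeq table given for the human assembly, which matched 41043 of the 41097, and none of its coordinates was used. No genome of the array design was used, so gene positions are not given. A gene was represented by its probe set with the highest mean over the 9 arrays, without the control probe sets of the array. Probe sets with the suffix _x_at or _s_at are called prone to cross-hybridisation here, and an alternative left them out. A suffix does not show that cross-hybridisation occurred. In that alternative a gene with such a probe set took a dimmer one or was dropped. Of 3873 genes with more than 1 measured probe set, 132 had a further probe set called in the opposite direction to the one used. Genes with a mean log2 intensity of at least 5 were kept.

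Log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 groups on all 9 arrays, 6 residual degrees of freedom, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists (38, of which 33 had at least 5 measured genes) were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The tests, gene lists, named genes and most alternatives were fixed before the data were examined. Named genes were the 10 highest and 10 lowest of nt-RNA against tc-RNA and the 5 highest and 5 lowest of the other comparisons, among called genes whose arrays did not overlap, with all called genes where fewer were found. For each described list they were the 3 brightest members and the 2 with the largest difference between nt-RNA and tc-RNA, and 12 genes were always named. Detection calls were not given. Where the dimmer fraction of a named gene had a mean log2 under 5, the report gives its difference as a bound, from values raised to log2 5 on each array where they lay under it. This floor was fixed in advance as an alternative, and its use for bounds was chosen after the data were seen.

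The share of new RNA was computed as c1 times the ratio of nt-RNA to tc-RNA, with the half-life as minus 60 min times ln 2 over the natural log of 1 minus that share. The scale factors c1 (0.114) and c2 (0.828) came from least squares of the p-RNA ratio on the nt-RNA ratio under the condition that both scaled fractions sum to 1. No correction for cell growth was made. The scale of the arrays does not enter the half-life, because c1 absorbs it.

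Arrays with the same replicate number deviated together from their group means. The correlations were 0.45, 0.53 and 0.54 for nt-RNA with tc-RNA, 0.42, 0.35 and 0.39 for nt-RNA with p-RNA, and 0.77, 0.66 and 0.85 for tc-RNA with p-RNA. The numbers were taken from the sample titles and treated as pairing the arrays, and the fit with the number as a block is given as an alternative. Arrays of number 3 stood apart, with an SD of differences from the others of the same fraction between 0.45 and 0.71 against 0.26 to 0.34 between numbers 1 and 2.

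The calculations were tested on simulated data with 200 changed genes among 8510. For nt-RNA against tc-RNA, limma recovered 6% of 1.41-fold, 54% of 2-fold, 88% of 4-fold and 96% of 8-fold changes, with 8 unchanged genes called. For p-RNA against tc-RNA the shares were 2%, 52%, 94% and 100%, and for nt-RNA against p-RNA 12%, 50%, 88% and 100%. In the real comparisons of nt-RNA far more than 200 genes were called, which makes the adjusted threshold less strict. The shares for nt-RNA are therefore not the recovery in these data. The half-life calculation returned the true median without noise and a longer one with noise, as given with the half-lives. Alternatives covered the filter, the scaling of arrays, the variance model, the choice of probe set, the replicate block, each array left out in turn and the half-life equation and regression. Figures were drawn with matplotlib 3.10.9.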

Results

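The series measured RNA turnover in BL41, an established human Burkitt lymphoma B-cell line. Cells were cultured for 60 min with 100 µM 4-thiouridine (4sU), a uridine analogue that is built into RNA made during the labelling time. Total cellular RNA (tc-RNA) was then separated into newly transcribed RNA (nt-RNA), which carries the label, and pre-existing RNA (p-RNA), which does not. Each of the 3 RNA fractions was hybridised to 3 arrays, 9 arrays in all. The title of the series gives the measurement of RNA half-lives as its aim. Of 19775 genes with a probe set of their own, 8510 had a mean log2 intensity of at least 5 and were tested. Median log2 intensity over these genes lay between 8.19 and 8.39 on the 9 arrays. The number of arrays limits the precision, and the median standard error of a difference between fractions was 0.22 on the log2 scale.

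The comparison of nt-RNA with tc-RNA asked which transcripts were over- or under-represented among RNA made in the last 60 min. Among called genes with a mean log2 of at least 5 in both fractions, the highest in nt-RNA was ZNF296, a zinc finger protein, at 12.4-fold (log2 difference 3.63 ± 0.34 SE, n = 3 arrays per fraction). DDIT3, a transcription factor of the stress response, was 12.1-fold higher (3.60 ± 0.23). The lowest was CYBA, a subunit of NADPH oxidase, at 12.6-fold lower (-3.65 ± 0.13). In all, 4650 of 8510 genes differed, 2251 higher and 2399 lower in nt-RNA (limma, Benjamini-Hochberg adjusted p under 0.05), and 1427 of the higher and 1284 of the lower genes differed by at least 2-fold. In 252 of the 4650 genes the dimmer fraction had a mean log2 under 5, where signal and background could not be told apart. The difference of such a gene is given as at least the one to a level of log2 5, and these genes have no order. In 59.9% of genes the 3 nt-RNA arrays did not overlap the 3 tc-RNA arrays, where chance gives 10%.

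Genes were named by a rule fixed in advance, without regard to that level. Further zinc finger proteins among those highest in nt-RNA were ZNF526 (11.3-fold), ZNF324 (11.2-fold), ZNF408 (11.1-fold), ZNF628 (at least 9.26-fold) and ZNF668 (at least 8.45-fold). The others were the phosphatase DUSP2 (11.5-fold), the mitochondrial prolyl-tRNA synthetase PARS2 (at least 9.34-fold) and MGC16275 (10.8-fold). The adjusted p-values of these genes as deposited lay between 1.16e-05 and 0.000171. Besides CYBA, those lowest in nt-RNA were TMEM256 (11.2-fold lower), SMG1P5 (10.6-fold lower), RIDA (9.88-fold lower) and the immunoproteasome subunit PSMB9 (8.68-fold lower). TRAPPC6A, a subunit of a vesicle tethering complex, was at least 11.5-fold lower, FAAP20 at least 8.85-fold lower, the biliverdin reductase BLVRB at least 5.97-fold lower, the annexin ANXA6 at least 3.89-fold lower and MPND at least 2.19-fold lower.

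Gene lists fixed before the data were examined moved in both directions, and 13 of 33 lists with at least 5 measured genes were called with camera at a preset inter-gene correlation of 0.01, 9 higher and 4 lower in nt-RNA. With an estimated correlation camera called 0 lists (4 at an unadjusted p under 0.05), and those adjusted p-values stand beside each list. The fry test, which does not compare a list with other genes, called 26, and camera without the intensity filter called 24. Shifts are given as the list median against the median of all genes, which was -0.04.

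Immediate early genes, which respond within minutes to signals, had the largest shift towards nt-RNA, with feedback inhibitors of signalling close to it. Of 19 measured members 18 were higher in nt-RNA and the list median lay 2.05 above that of all genes (adjusted p = 3.44e-08, and adjusted p = 0.168 with an estimated correlation). DUSP2 and IER2 (7.09-fold) changed most, and among the brightest members BTG1 was 2.68-fold, MYC 4.10-fold and ID2 4.20-fold higher. Feedback inhibitors of signalling were higher in 8 of 11 members (shift 2.02, adjusted p = 0.00109, and adjusted p = 0.352 with an estimated correlation), with RGS16 at 8.12-fold, SOCS1 at 4.98-fold or more, RGS2 at 5.44-fold, TRIB3 at 4.12-fold and SPRED2 at 3.27-fold. NF-κB feedback genes and targets were higher in 13 of 20 members and lower in 1 (shift 1.25, adjusted p = 0.00118, and adjusted p = 0.352 with an estimated correlation). GADD45B was 10.2-fold, NFKBIE 7.63-fold, the inhibitor NFKBIA 6.32-fold, CD83 2.94-fold and TNFAIP8 1.87-fold higher. The call of this list was lost without probe sets prone to cross-hybridisation (shift 0.80, adjusted p = 0.147).

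Zinc finger transcription factors formed the largest of these groups. Of 55 measured members 41 were higher and 2 lower (shift 1.30, adjusted p = 5.75e-10, and adjusted p = 0.320 with an estimated correlation). ZNF134 was 6.96-fold, ZNF16 at least 6.16-fold, ZNF593 2.24-fold and ZNF107 1.55-fold higher, though ZNF107 was lower with the median of its probe sets (log2 difference -1.42, adjusted p = 0.00403), while ZNF146, the brightest, did not pass the test (log2 difference 0.21 ± 0.17). Cytokines, chemokines and their receptors were higher in 17 of 22 members and lower in 1 (shift 1.45, adjusted p = 0.000293, and adjusted p = 0.352 with an estimated correlation). CCL4 was 6.82-fold (a call lost without replicate 1 or 2 of nt-RNA or replicate 3 of tc-RNA, at log2 differences of 2.32, 2.33 and 2.09 and adjusted p-values of 0.0644, 0.0641 and 0.0537, against 2.77 with all arrays), IL10RA 6.51-fold, CXCR4 3.08-fold and TNFRSF17 2.71-fold higher, and the cytokine MIF was 2.05-fold lower. B-cell transcription factors were higher in 11 of 24 members (shift 0.51, adjusted p = 0.0238, and adjusted p = 0.468 with an estimated correlation). ID3 was 6.29-fold, BCL6 3.66-fold and PAX5 1.65-fold higher, the last not called with the median of its probe sets (log2 difference 0.30, adjusted p = 0.0796), whereas POU2AF1 (log2 difference -0.20 ± 0.16) and ETS1 (-0.31 ± 0.16, and adjusted p = 0.0298 with the replicate block) did not pass the test. Without probe sets prone to cross-hybridisation the shift of this list was 0.09 (adjusted p = 0.217).

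A further 3 lists were called as higher in nt-RNA. Ubiquitin ligases and F-box proteins were higher in 25 of 50 members and lower in 4 (shift 0.62, adjusted p = 0.00227, and adjusted p = 0.352 with an estimated correlation), with FBXO42 at 4.23-fold, FBXL12 at 4.11-fold and UBE3A at 1.85-fold. The call of UBE3A was lost with the median of its probe sets (log2 difference 0.24, adjusted p = 0.147). HUWE1 and CUL3 did not pass the test (log2 differences 0.05 and 0.28). Chromatin modifiers were higher in 22 of 48 members and lower in 6 (shift 0.58, adjusted p = 0.0121, and adjusted p = 0.168 with an estimated correlation). BRD2 was 4.52-fold and KDM6B at least 3.02-fold higher and HDAC1 1.69-fold lower, and SMARCA4 and DNMT1 did not pass the test (-0.0022 and -0.29). Circadian and related bHLH factors were higher in 7 of 15 members (shift 0.66, adjusted p = 0.0151, and adjusted p = 0.322 with an estimated correlation), among them NFIL3 (5.54-fold), CRY2 (at least 4.41-fold) and MLX (3.14-fold). MAX and PER2 did not pass the test (-0.25 and 0.62, the latter at an adjusted p of 0.00721 with the replicate block and at 0.91 with an adjusted p of 0.0131 without replicate 3 of nt-RNA). With the median of its probe sets MAX was lower in nt-RNA (log2 difference -1.67, adjusted p = 2.78e-05). The circadian list was not called at a mean log2 of at least 7, where its shift was 1.57 (adjusted p = 0.0615).

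The 4 lists called as lower in nt-RNA were oxidative phosphorylation, the tricarboxylic acid cycle, the proteasome and cytosolic ribosomal proteins. Oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, were lower in 57 of 64 members and higher in 1 (shift -1.17, adjusted p = 7.69e-14, and adjusted p = 0.168 with an estimated correlation). NDUFA3 was 5.17-fold, NDUFB1 4.91-fold and COX6A1 1.61-fold lower, and ATP5F1A and CYCS did not pass the test (-0.17 and -0.06). Enzymes of the tricarboxylic acid cycle were lower in 17 of 19 members (shift -1.31, adjusted p = 3.27e-05, and adjusted p = 0.322 with an estimated correlation), with ACO1 at 3.76-fold, IDH2 at 3.74-fold, MDH1 at 2.82-fold, DLD at 2.58-fold and MDH2 at 1.52-fold lower. MDH2 was not called with the median of its probe sets (log2 difference -0.32, adjusted p = 0.0643) or without those prone to cross-hybridisation (-0.049, adjusted p = 0.841). The call of IDH2 was lost without replicate 1 or 2 of nt-RNA or replicate 3 of tc-RNA (log2 differences -1.55, -1.57 and -1.59, adjusted p-values 0.0615, 0.0610 and 0.0529, against -1.90 with all arrays). Proteasome subunits were lower in 22 of 34 members (shift -0.63, adjusted p = 3.27e-05, and adjusted p = 0.370 with an estimated correlation). PSMA5 was 3.20-fold, PSME1 2.95-fold and PSMB1 1.58-fold lower, the last not called with the median of its probe sets (log2 difference -0.26, adjusted p = 0.102), and PSMB4 and PSMC2 did not pass the test (-0.27 and 0.02). For PSMB4 the adjusted p was 0.0399 with the replicate block, and leaving out replicate 1 or 2 of nt-RNA, replicate 1 of tc-RNA or replicate 1 of p-RNA made another of its probe sets the brightest, with log2 differences of -0.88, -0.93, -1.02 and -0.98. With the median of their probe sets PSMB4 was at -0.76 (adjusted p = 0.00271) and PSMC2 at -0.89 (adjusted p = 0.00380). Cytosolic ribosomal proteins were lower in 29 of 51 members (shift -0.38, adjusted p = 3.49e-05, and adjusted p = 0.488 with an estimated correlation). This call was lost with the median of all probe sets (shift -0.22, adjusted p = 0.0814) and without those prone to cross-hybridisation, where the shift was as large (-0.39, adjusted p = 0.203). RPL36 was 2.32-fold and RPS21 2.29-fold lower, though RPS21 was higher without such probe sets (log2 difference 1.92, adjusted p = 0.000516), and RPL7, RPS18 and RPL41 did not pass the test (-0.25, -0.21 and -0.06). With the replicate number as a block the glycolysis list was called as well (adjusted p = 0.0258, against 0.0892 without the block, and adjusted p = 0.633 with an estimated correlation and no block).

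**Figure D1:**
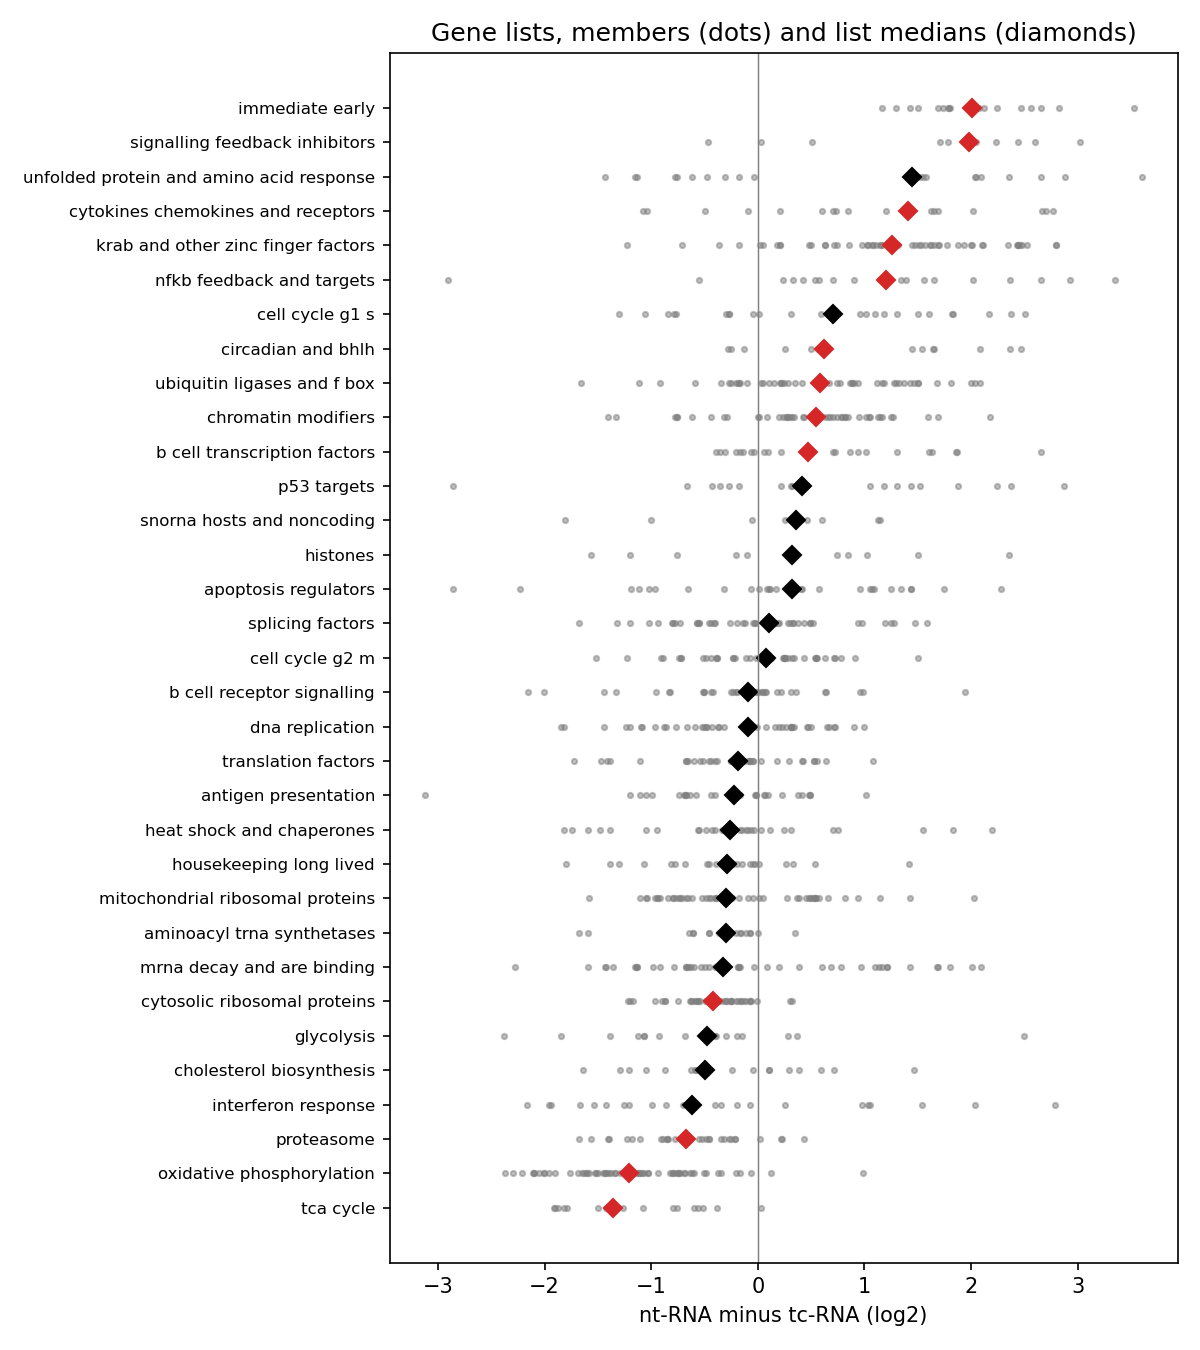
Each row is 1 of the 33 gene lists, grey dots are measured members and diamonds list medians of the log2 difference between nt-RNA and tc-RNA (x axis), red where camera called the list. Immediate early genes lie at a median of 2.01 and the tricarboxylic acid cycle at -1.36.

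Adjusted over the list alone, the member counts were unchanged for 10 of the 13 lists. NF-κB genes then had 15 higher members, circadian factors 6 higher and oxidative phosphorylation 58 lower. Among genes chosen in advance, MYC, IER2 and NFKBIA were higher in nt-RNA as given above, and JUN (3.49-fold), the cell cycle inhibitor CDKN1A (5.18-fold) and the survival factor MCL1 (2.38-fold) were higher too. A dimmer probe set of MCL1 (mean log2 5.47) was called by limma as lower (log2 difference -0.68, adjusted p = 0.0464). ACTB (log2 difference 0.01 ± 0.14), GAPDH (-0.15 ± 0.13), B2M (-0.03 ± 0.13), LDHA (-0.19 ± 0.16) and TFRC (0.33 ± 0.13, adjusted p = 0.0528, 0.0229 with the replicate block, and 0.0112 without replicate 3 of nt-RNA) did not pass the test, and centring on ribosomal proteins turned the sign of GAPDH, B2M and LDHA and centring on hybridisation controls that of ACTB and TFRC. With the median of their probe sets B2M (log2 difference -0.59, adjusted p = 0.0175) and TFRC (-1.37, adjusted p = 0.00299) were lower in nt-RNA. FOS had a mean log2 intensity under 5 and was not tested. The 3′ minus 5′ log2 signal of the ACTB control probe sets was 1.25 ± 0.56 (SD, n = 3) in nt-RNA, 0.43 ± 0.02 in tc-RNA and 0.49 ± 0.03 in p-RNA, and that of GAPDH was 0.38 ± 0.25, -0.26 ± 0.05 and -0.19 ± 0.06, so that this measure moved with nt-RNA beside each of the 13 lists above (exact permutation p = 0.1, two-sided, the smallest 3 against 3 arrays allow).

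**Figure D2:**
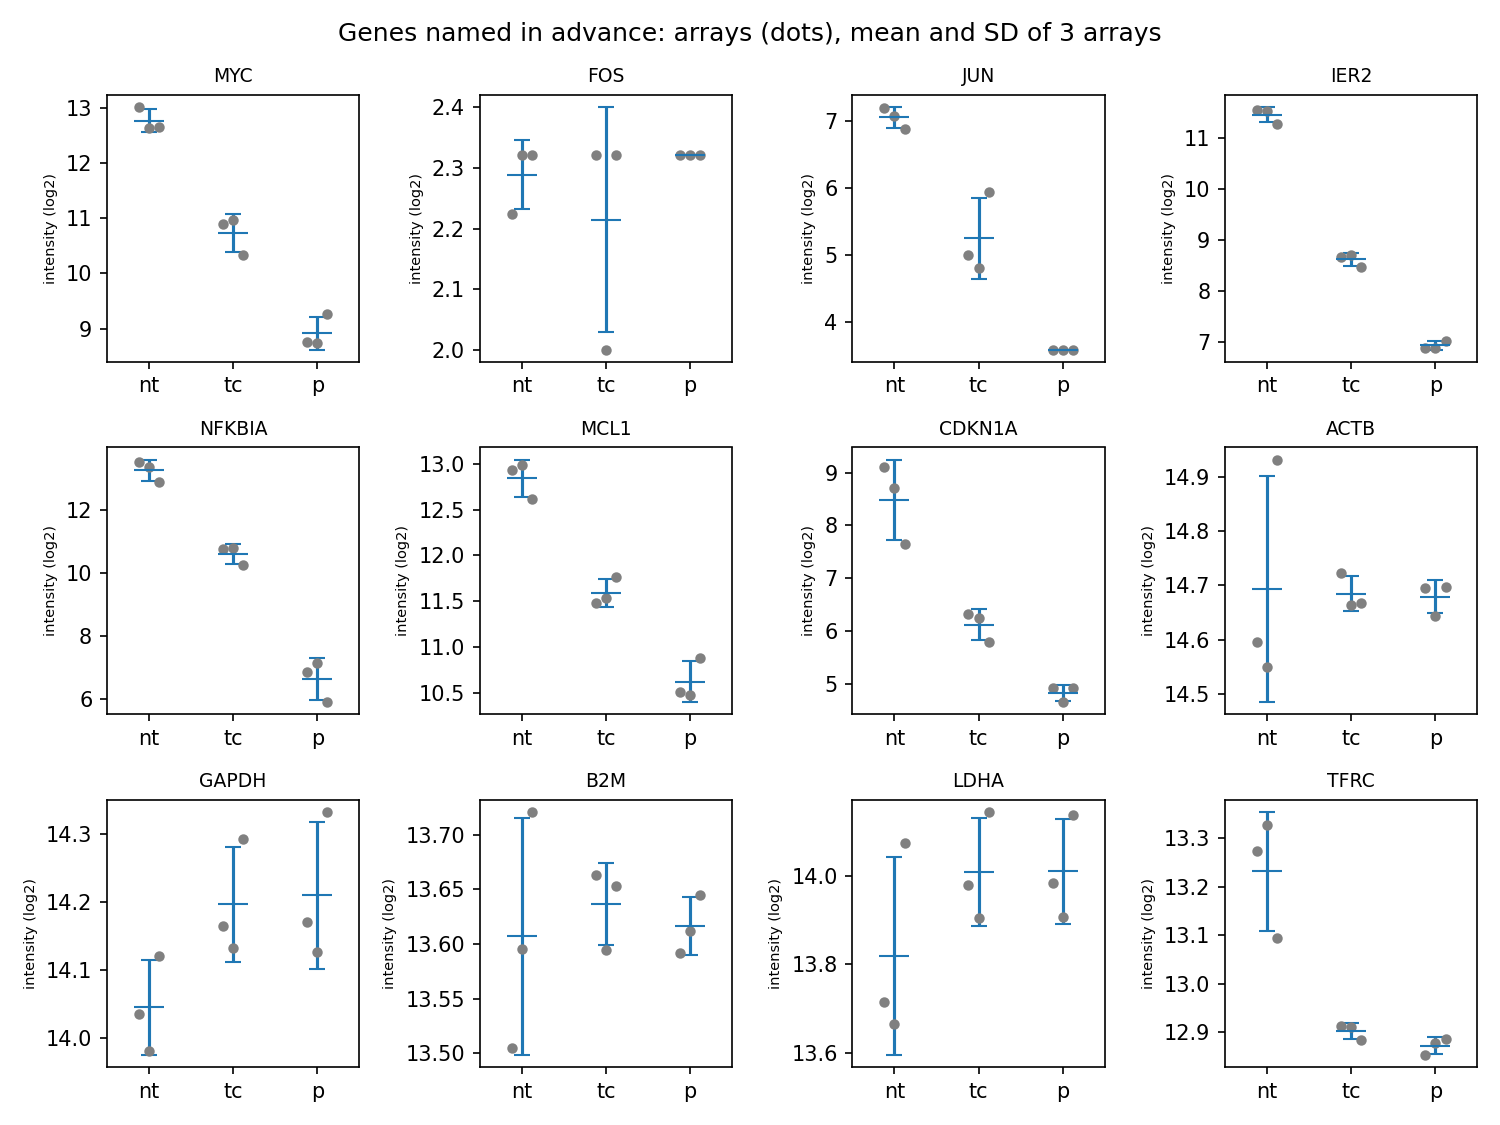
Log2 intensity (y axis) of 12 genes chosen in advance in the 3 fractions (x axis), each panel with its own scale, with dots for arrays and bars for mean and SD of 3 arrays. IER2 is 7.09-fold higher in nt-RNA than in tc-RNA, and ACTB differs by 0.01 on the log2 scale.

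With each array centred on cytosolic ribosomal proteins 76.3% of calls were higher in nt-RNA, and with centring on bacterial hybridisation controls 25.8%, against 48.4% as deposited, because these scalings moved the median of all genes by 0.43 and -0.39. Ribosomal protein centring ended the calls of COX6A1, HDAC1, IDH2, MDH2 and PSMB1 (log2 differences -0.26, -0.32, -1.47, -0.17 and -0.22, adjusted p-values 0.142, 0.165, 0.0575, 0.505 and 0.231) and added CUL3, HUWE1, PER2, PSMC2, RPL41, TFRC and ZNF146 as higher. Hybridisation control centring ended those of PAX5, TNFAIP8, UBE3A, ZNF107 and ZNF593 (log2 differences 0.33, 0.51, 0.49, 0.24 and 0.77, adjusted p-values 0.294, 0.135, 0.118, 0.462 and 0.0836) and added ETS1, PSMB4 and RPL7 as lower. The mean log2 of these controls was 10.45 on nt-RNA replicate 1 and 11.01 and 11.13 on replicates 2 and 3. This centring thus moved the nt-RNA arrays unequally, and calls can also be lost through the wider spread between them.

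The comparison of p-RNA with tc-RNA asked which transcripts were depleted from the pool made before the label was added. Among called genes with a mean log2 of at least 5 in both fractions, NFKBIA was the lowest in p-RNA, at 15.7-fold lower (log2 difference -3.97). The genes named as lowest by the rule had p-RNA means under log2 5 and no order. The kinase SGK1 was at least 17.9-fold lower, TAF1D, a subunit of an RNA polymerase I factor, at least 17.7-fold, TAGAP at least 14.5-fold, SFXN3 at least 5.50-fold and the chaperone DNAJB9 at least 4.81-fold lower. For SGK1, TAF1D, SFXN3 and DNAJB9 the scaled nt-RNA and p-RNA together came to 0.42, 0.15, 0.33 and 0.36 of tc-RNA. Much of the RNA missing from their p-RNA was thus not found in nt-RNA, and their low p-RNA need not reflect fast turnover. TAF1D did not pass the test in nt-RNA against tc-RNA (0.23, 0.88 at an adjusted p of 0.0127 without replicate 3 of nt-RNA, 0.38 without replicate 2 of tc-RNA, and negative without replicate 1 or 2 of nt-RNA or replicate 3 of tc-RNA). MYC was 3.51-fold and IER2 3.21-fold lower. Of 8510 genes 394 differed, 392 lower and 2 higher in p-RNA, and 334 of the lower genes differed by at least 2-fold. In 132 of the 392 the p-RNA mean was under log2 5. If both scaled fractions sum to 1, the ratio of p-RNA to tc-RNA cannot exceed 1 over c2 (0.828). That ceiling is under 1.41-fold, a change of which limma recovered 2% in simulated data. Few genes could thus be called as higher, whatever their turnover. The 2 higher genes, both above the ceiling, were FUOM (log2 difference 0.65, adjusted p = 0.0422) and SIGIRR (0.57, adjusted p = 0.0428). Both calls were lost under centring on the median, on ribosomal proteins or on hybridisation controls, with a variance trend in eBayes (adjusted p-values 0.134 and 0.132) and without any 1 of replicates 1 and 2 of nt-RNA, all tc-RNA arrays and replicates 1 and 2 of p-RNA, with adjusted p-values up to 0.190 for FUOM and 0.209 for SIGIRR without an array. In these settings the log2 differences lay between 0.53 and 0.74 for FUOM and between 0.46 and 0.62 for SIGIRR. FUOM was also lost in a fit of the 2 groups alone (adjusted p = 0.0584), and SIGIRR without probe sets prone to cross-hybridisation (adjusted p = 0.0530) or without replicate 3 of p-RNA (adjusted p = 0.0876).

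Of 33 lists 12 were called, 10 lower and 2 higher in p-RNA, and 7 of the 9 lists that were higher in nt-RNA were among the 10. Immediate early genes were lower in 17 of 19 members (shift -2.36, adjusted p = 2.25e-29), and this list alone was called with an estimated correlation (adjusted p = 0.0197). Zinc finger factors were lower in 22 of 55 members (shift -0.82, adjusted p = 1.61e-25, and adjusted p = 0.0873 with an estimated correlation) and feedback inhibitors in 5 of 11 (shift -1.09, adjusted p = 5.94e-10, and adjusted p = 0.142 with an estimated correlation). Oxidative phosphorylation (shift 0.07, adjusted p = 0.00371, and adjusted p = 0.477 with an estimated correlation) and mitochondrial ribosomal proteins (shift 0.03, adjusted p = 0.0268, and adjusted p = 0.496 with an estimated correlation) were called as higher by camera, while limma called 0 of their members one by one (0 higher and 1 lower in each list at an unadjusted p under 0.05). The fry test called 8 lists.

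The count of genes called between p-RNA and tc-RNA was 604 with the replicate number as a block (45 higher and 559 lower), 740 without replicate 3 of all fractions, a choice made after the data were seen, 224 without replicate 2 of tc-RNA, 246 without replicate 1 and 250 without replicate 2 of p-RNA, 251 at a mean log2 of at least 7 and 2699 with no filter, of which 2163 were higher. With no filter, 4 genes were higher by at least 2-fold. Centring each array on its median moved the median difference of all genes by -0.11.

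The direct comparison of nt-RNA with p-RNA used the tc-RNA arrays only for the filter, the choice of probe set and the shared estimate of spread, and a fit of the 2 groups alone called 5134 genes. Among called genes with a mean log2 of at least 5 in both fractions, NFKBIA was the highest in nt-RNA (log2 difference 6.63 ± 0.33) and CYBA the lowest (-3.83). Of the other genes named by the rule, the G-protein regulator RGS16 was at least 99.9-fold, TAGAP at least 76.3-fold, SGK1 at least 61.9-fold and DUSP2 at least 44.9-fold higher. TRAPPC6A was at least 15.7-fold, FAAP20 at least 11.1-fold, ANXA6 at least 5.41-fold and MPND at least 3.27-fold lower. In all, 5485 genes differed, 2505 higher and 2980 lower in nt-RNA, with 1800 and 1799 of them by at least 2-fold, and in 498 the dimmer fraction had a mean log2 under 5. Of 33 lists 16 were called, 12 higher and 4 lower, and 0 with an estimated correlation (4 at an unadjusted p under 0.05, and 27 with fry). Immediate early genes were higher in 19 of 19 members (shift 4.48, adjusted p = 2.93e-11, and adjusted p = 0.185 with an estimated correlation). Ribosomal protein centring made 69.3% of calls higher in nt-RNA, and hybridisation control centring 30.0%, against 45.7% as deposited.

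Across genes, the ratios of p-RNA and of nt-RNA to tc-RNA ran in opposite directions. The Pearson correlation of the log2 ratios was -0.59 and the Spearman correlation -0.67 over 8510 genes, which are not independent replicates. With no intensity filter they were -0.52 and -0.31. Unchanged groups that share the tc-RNA arrays gave 0.50 and 0.46 in 100 simulations of independent arrays. With arrays of one number deviating together as observed, a simulation added after the data were seen, they gave 0.18 and 0.16. The covariance was -0.31, against 0.04 and 0.0052 simulated. Of 2251 genes higher in nt-RNA, 323 were also lower in p-RNA, where independent lists give 103.7. Both comparisons used the same tc-RNA arrays, so 103.7 is not an exact value for no relation. With 1 tc-RNA array under one ratio and the other 2 under the other, a check added after the data were seen, the Pearson correlation lay between -0.66 and -0.51 and the Spearman correlation between -0.74 and -0.48 in the 6 splits. For the calls the arrays were too few to split.

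**Figure D3:**
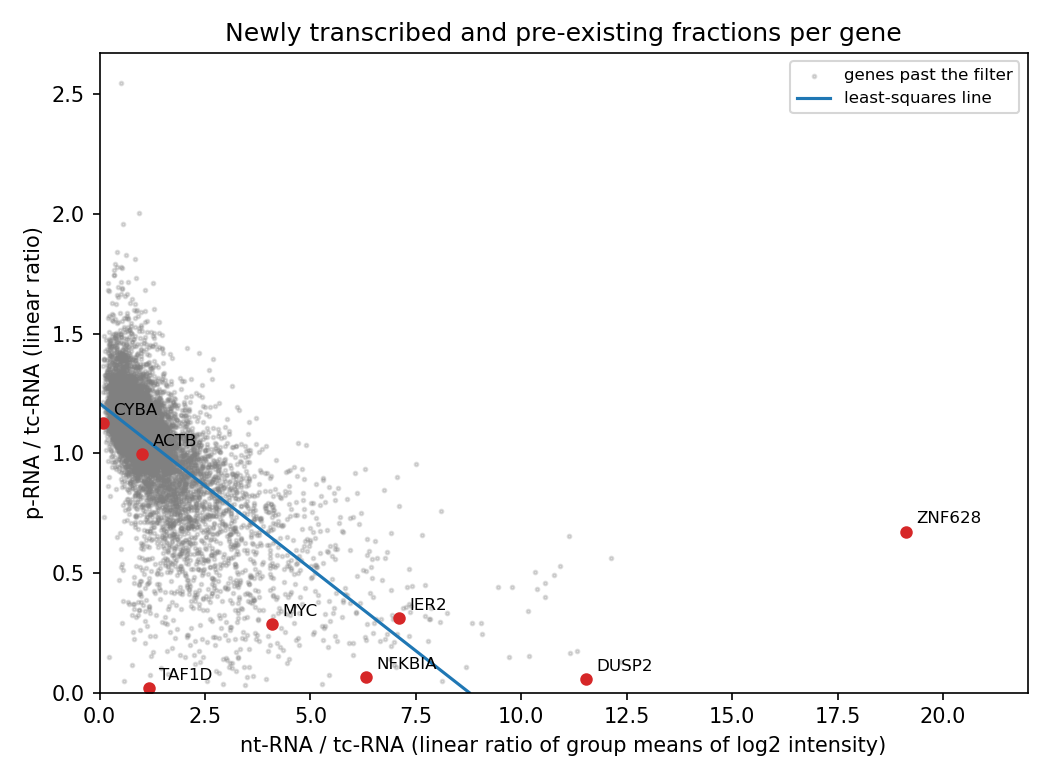
Ratio of nt-RNA to tc-RNA (x axis) against ratio of p-RNA to tc-RNA (y axis), both linear, for 8510 genes, with the least-squares line and 8 genes in red, of which ZNF628 and TAF1D have a fraction with a mean log2 under 5 and hence no exact place. NFKBIA lies at a high nt-RNA ratio of 6.32 and a low p-RNA ratio, and ACTB near 1 on both axes.

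Half-lives were computed from the nt-RNA ratio with scale factors fitted from this relation. The median was 5.89 h over 8510 genes, the middle 50% of genes lay between 3.44 h and 9.34 h, and 888 genes (10.4%) were under 2 h, among them 21 whose computed new share reached 100% and whose half-life was set to 0. Immediate early genes had a median of 1.12 h and feedback inhibitors 1.16 h, whereas the medians were 13.7 h for oxidative phosphorylation and 15.2 h for the tricarboxylic acid cycle. IER2 had a half-life of 0.42 h, NFKBIA 0.54 h, MYC 1.10 h, MCL1 2.19 h, ACTB 5.69 h and GAPDH 6.39 h. Each value rests on the nt-RNA ratio of 1 probe set. ACTB and GAPDH had mean log2 intensities of 14.7 and 14.2. At such brightness the ratios spread less and saturation was not excluded, as given below. Their half-lives may thus be those of ratios drawn towards 1. All half-lives here hold only if RNA levels were steady during labelling, which was not tested. The p-RNA ratio, not used for single genes here, can give other values. Position of the probes mattered as well. The log2 difference between nt-RNA and tc-RNA was -0.03 for the 3′ and -0.85 for the 5′ control probe set of ACTB. For GAPDH these were 0.07 and -0.57, so 5′ signals would give longer half-lives. Calculated for each replicate number alone, the median was 6.68 ± 1.08 h (SD, n = 3), and 9.55%, 12.6% and 4.99% of genes were under 2 h in numbers 1, 2 and 3. The share of genes under 2 h was 18.4% when computed from the p-RNA ratio and 4.71% with no filter.

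In simulated data array noise disturbed the absolute scale of half-lives more than the order of the genes. The Spearman correlation of true half-lives with the nt-RNA ratio, its sign turned, was 0.94 to 0.98 with noise. The simulation held array noise only. The order of the real genes was not tested against other errors, such as 4sU capture that depends on transcript length or uridine number. With a true median of 5.95 h, the same calculation returned 5.95 h without array noise. It returned 7.02 h with noise as small as within replicate numbers. With noise as large as between all arrays of a fraction it returned 21.01 h. This larger noise was independent between arrays, although real arrays of one number deviated together. Both ratios then correlated at -0.36, against -0.53 with the smaller noise and -0.59 observed. With a narrower spread of half-lives (true median 5.96 h) the calculation returned 7.99 h with the smaller noise and no finite value with the larger. The share under 2 h came out too low, at 6.46% and 0.059% with the 2 noise levels where 9.14% was true, and at 1.41% and 0 where 3.92% was true, so the share of 10.4% may be too low as well. By the same simulations the median of 5.89 h and the half-lives of lists and genes may be too long.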

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

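The tests of these signals were chosen after the gene results had been seen. The control probe sets and the probe sets without a single gene name were not part of the comparisons, and some of them had signals above those in tc-RNA. Others were lower in nt-RNA, among them the probe set for the 3′ part of the ISGF3A control (-0.91, adjusted p = 0.00252). The 2 middle probe sets of this control were called too (-1.33 and -1.39, adjusted p-values 0.00281 and 0.000713). Their mean intensities were 11.3 and 13.7 in nt-RNA and 28.5 and 35.9 in tc-RNA, where log2 5 is 32. Signal and background could not be told apart under that level, so these 2 differences are not exact. The 5′ probe sets of ACTB (-0.85, adjusted p = 0.0429) and GAPDH (-0.57, adjusted p = 0.0298) were lower as well. The Alu repeat control was 0.33 higher on the log2 scale in nt-RNA than in tc-RNA and did not pass the test (adjusted p = 0.0647), at mean intensities of 26365 and 20978, against 13174 in p-RNA, where it was lower than in tc-RNA (-0.67, adjusted p = 0.0198). Hybridisation controls moved as far, with the 5′ probe set for cre at 0.45 (adjusted p = 0.0295). The mean log2 over these controls was 10.45, 11.01 and 11.13 on nt-RNA replicates 1, 2 and 3. On the tc-RNA arrays it was 10.43 to 10.49, so replicate 1 did not move in this mean. The 28S rRNA control was 1.61 higher in nt-RNA for the 5′ part (adjusted p = 0.00137) and 1.17 for the middle (adjusted p = 0.000939), with the 3′ part at a mean log2 of 1.58. The 18S rRNA control was 1.62 higher for the 3′ part (adjusted p = 0.000277) and 1.08 for the middle (adjusted p = 0.0149), while the 5′ part did not pass the test (0.37, adjusted p = 0.341). Of 1373 probe sets outside the gene table that passed the filter, 199 (14.5%) were higher and 399 (29.1%) lower in nt-RNA, against 22.6% and 30.0% of probe sets with 1 gene. In p-RNA 288 (20.98%) were lower, against 5.16%. Of 802 probe sets that name several genes, 217 (27.1%) were higher and 211 (26.3%) lower in nt-RNA, with a median difference of -0.0015. The poly-A spike controls for dap, lys, phe and thr, RNAs of bacterial genes that are added during preparation, were seen on replicate 1 of each fraction only. The 3′ probe set for dap had intensities of 6865 in nt-RNA, 2384 in tc-RNA and 2679 in p-RNA on these arrays, against 5 or 6 on the other 6 arrays. The arrays of number 1 thus differed from the others in their preparation, which adds to the hint that a number stands for arrays handled together.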

How the results depend on the processing

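The scaling on hybridisation controls and the omission of replicate 3 of all fractions were chosen after the data were seen, and the other alternatives before. The numbers of genes called for nt-RNA against tc-RNA (3216 to 5849) and nt-RNA against p-RNA (3868 to 6705) stayed within 1.5 times those reported under the alternatives run. The Pearson correlation between both ratios stayed negative, at -0.61 to -0.52. The settings were the filters, median centring, quantile normalization, other choices of probe set, the replicate block and each array left out. The Spearman correlation was -0.31 with no filter, against -0.67 as reported. For p-RNA against tc-RNA the number was 2699 with no filter, 251 at a mean log2 of at least 7, 604 with the replicate block, 740 without replicate 3 of all fractions and between 224 and 554 with single arrays left out. With at least 2-fold it was 200 at the higher filter and between 212 and 383 with single arrays left out. The larger number with no filter came with 19775 genes tested. Of the 2699 genes, 2163 were higher in p-RNA, and 4 were higher by at least 2-fold. Median intensity over all probe sets was 9 on p-RNA replicates 1 and 3, and 8 on replicate 2 and the tc-RNA arrays. Whether these small differences reflect background was not tested. The median half-life lay between 309 and 407 min, each less than the SD between replicate numbers (65.0 min) from the 354 min reported, and the share under 2 h was 4.71% with no filter and 18.4% from the p-RNA ratio. Settings can share the bias towards long half-lives seen with simulated noise, so this range does not show that the median is right. Camera called 24 lists with no filter and 0 with an estimated correlation, and fry 26.

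With the replicate number as a block, 4647 of the 4650 genes called between nt-RNA and tc-RNA, 390 of 394 between p-RNA and tc-RNA and 5481 of 5485 between nt-RNA and p-RNA were called again. Among the named genes and the lists of nt-RNA against tc-RNA, the block added the calls of glycolysis, ETS1, LCK, PER2, PSMB4 and TFRC and changed no other call. With the median of all probe sets B2M was called as lower (adjusted p = 0.0175). A variance trend added PSMB4, RPL7, RPS18 and TFRC. No filter added PSMB4, RPL7 and TFRC and ended the calls of CCL4 and IDH2. Their log2 differences were unchanged at 2.77 and -1.90 (adjusted p-values 0.0752 and 0.0688). The higher filter added TFRC, and quantile normalization CUL3 and TFRC. The omission of replicate 3 of all fractions added LCK, PER2, TAF1D, TFRC and ZNF146. It also added the lists of glycolysis, aminoacyl-tRNA synthetases, p53 targets, chaperones and housekeeping genes.

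The direction of the camera test turned for 3 lists that were not called. For G2/M genes the list shift was then 0.049 with no filter, 0.026 with the median of all probe sets, 0.0089 without probe sets prone to cross-hybridisation, 0.094 without replicate 3 of all fractions and 0.12 with hybridisation control centring (0.0071 to 0.19 with single arrays left out). For splicing factors it was 0.16 at the higher filter, 0.22 with quantile normalization, 0.15 with ribosomal centring and 0.15 with the replicate block (0.0050 to 0.16 with single arrays left out). For histones it was -0.037 at the higher filter.

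The sign of the difference between nt-RNA and tc-RNA turned for named genes as follows, and except where the setting itself moves all genes the cause was not tested. With median centring ACTB was at -0.0068. With quantile normalization ACTB was at -0.046, B2M at 0.15, ATP5F1A at 0.0090, CYCS at 0.094 and SMARCA4 at 0.14. With centring on ribosomal proteins GAPDH was at 0.28, B2M at 0.40, LDHA at 0.24, POU2AF1 at 0.23, ETS1 at 0.13, RPL7 at 0.18, RPS18 at 0.23, RPL41 at 0.37, ATP5F1A at 0.26, CYCS at 0.37, PSMB4 at 0.16, SMARCA4 at 0.43, DNMT1 at 0.15 and MAX at 0.18. With hybridisation control centring ACTB was at -0.39, TFRC at -0.067, ZNF146 at -0.18, PSMC2 at -0.38, HUWE1 at -0.35, TAF1D at -0.17 and CUL3 at -0.11. With the median of all probe sets ACTB was at -0.031, TFRC at -1.37, ZNF146 at -0.22, ZNF107 at -1.42, RPS21 at 0.36, PSMC2 at -0.89, CUL3 at -0.62 and TFDP1 at 0.092. Without probe sets prone to cross-hybridisation B2M was at 1.07, ZNF107 at -1.42, RPL7 at 0.35, RPS21 at 1.92 and PSMC2 at -0.89. Without replicate 3 of all fractions ACTB was at -0.099 and PSMC2 at -0.036. With single arrays left out ACTB lay between -0.093 and 0.079, B2M between -0.086 and 0.021, PSMC2 between -0.039 and 0.067, RPL41 between -0.11 and 0.014, TAF1D between -0.13 and 0.88 and SMARCA4 between -0.32 and 0.19.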

Other observations

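The gene lists, most of their alternatives, the intensity-matched lists and the other splits of the arrays were fixed before the data were examined. The other tests in this part were chosen after results were seen, as was the use of the probe-set alternative as a test of cross-hybridisation.

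Lists that camera did not call held genes with opposite behaviour. Genes of the unfolded protein and amino acid response were higher in nt-RNA in 12 of 22 members and lower in 6 (adjusted p = 0.0516). This list was called with median centring (adjusted p = 0.0427), hybridisation control centring (adjusted p = 0.00740), no filter (adjusted p = 0.0103) and without any 1 of replicates 1 and 2 of nt-RNA and the 3 tc-RNA arrays (adjusted p-values 0.0340 to 0.0468), but not with an estimated correlation. DDIT3 was 12.1-fold, PPP1R15A at least 7.04-fold, HERPUD1 4.26-fold and ATF4 2.98-fold higher, whereas the asparagine synthetase ASNS was 2.22-fold lower. Interferon response genes were lower in 13 of 24 members and higher in 5 (adjusted p = 0.141), with IFI44 at least 1.70-fold lower and IRF1 6.92-fold higher. Regulators of the G1/S transition were higher in 13 of 25 and lower in 5 (adjusted p = 0.0683), with CDT1 5.68-fold higher and TFDP1 2.47-fold lower, though with the median of its probe sets TFDP1 was at 0.092 on the log2 scale. Apoptosis regulators were higher in 11 of 29 and lower in 5 (adjusted p = 0.183), with FADD 4.87-fold higher and BAX 7.23-fold lower. The adjusted p-values of the other lists were 0.0683 for p53 targets and for aminoacyl-tRNA synthetases, 0.0892 for glycolysis, 0.105 for translation factors and for housekeeping genes, 0.154 for chaperones, 0.157 for antigen presentation, 0.183 for cholesterol synthesis and 0.201 for mitochondrial ribosomal proteins. They were 0.378 for DNA replication and for mRNA decay factors, 0.464 for B-cell receptor signalling, 0.507 for noncoding RNAs, 0.658 for G2/M genes, 0.738 for histones and 0.833 for splicing factors, where the median of the list was positive and the test negative. Without the filter camera also called antigen presentation, aminoacyl-tRNA synthetases, cholesterol synthesis, DNA replication, glycolysis, chaperones, housekeeping genes, mitochondrial ribosomal proteins, mRNA decay and translation factors, all lower. Hybridisation control centring added aminoacyl-tRNA synthetases, G1/S regulators and p53 targets, and ribosomal protein centring interferon response genes. Aminoacyl-tRNA synthetases, glycolysis and housekeeping genes were called without replicate 3 of nt-RNA, and aminoacyl-tRNA synthetases, p53 targets and translation factors without replicate 3 of tc-RNA. With an estimated correlation and the filter, the adjusted p-values of these lists lay between 0.370 and 0.738.

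Most markers of other cell types had a mean log2 intensity under 5. The 3 that passed are named here after their values were seen. Of 18 T and NK cell markers 1 passed the filter (LCK, log2 difference between nt-RNA and tc-RNA -0.82, adjusted p = 0.146, 0.0427 with the replicate block, and -1.42 at an adjusted p of 0.000604 without replicate 3 of nt-RNA and -1.21 at 0.0156 with hybridisation control centring), of 13 myeloid markers 0, of 13 epithelial and fibroblast markers 2 (COL1A1, 3.24-fold higher in nt-RNA and not called with the median of its probe sets at an adjusted p of 0.575, and VIM, 2.78-fold lower and not called with centring on ribosomal proteins at -1.04) and of 4 erythroid markers 0. A further 2 myeloid and 6 erythroid markers of these lists had no probe set of their own.

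At the preset correlation 9 lists were shifted towards nt-RNA and 4 away from it, and with an estimated correlation 0 of 33 were called. Array intensity of the listed genes was argued against as the whole cause. Of the 13 called lists 12 lay outside the central 95% of 10000 random lists matched on intensity, the circadian list being the exception. Cytosolic ribosomal proteins and the proteasome lay close to the limit, with medians of -0.42 and -0.67 against lower limits of -0.41 and -0.63. The medians of their matched lists were -0.26 and -0.31. Random lists were drawn without correlation between genes, so their range may be too narrow. Probe sets prone to cross-hybridisation were argued against as the whole cause, since 10 of the 13 lists were still called without them. Leaving out the suffixes _x_at and _s_at also gave some genes a dimmer probe set and dropped others. A call lost in this setting therefore need not come from cross-hybridisation. Transcription induced by 4sU itself stays open, because the design has 0 arrays of cells without 4sU, and fast turnover of the regulators may underlie the shift as an untested hypothesis.

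Ratios of nt-RNA to tc-RNA spread less among genes with the brightest probe sets. The SD of the difference between nt-RNA and tc-RNA fell from 1.12 at a mean log2 of 5 to 0.39 at 13 or more, where the median difference was -0.29 and 43.6% of genes were called. Dimmer probe sets of the bright genes had an SD 2.06 times that of the brightest, against 1.27 times in genes of middle intensity, which saturation may explain, but they followed the brightest only weakly (r = 0.17, 95% bootstrap interval -0.08 to 0.40, against 0.67 in genes of middle intensity). Among probe sets at least 1 log2 unit dimmer, a selection made after the first was seen, the ratio was 2.36 and r 0.02, against 1.33 and 0.64 in genes of middle intensity. The bright hybridisation controls (mean log2 14.1 in tc-RNA) moved by 0.55 and the dim ones (8.17) by 0.58 in nt-RNA replicates 2 and 3. That goes against saturation at this brightness, whereas the wider SD of the dimmer probe sets goes with it. Saturation and other transcripts under the dimmer probe sets were therefore not told apart.

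In 104 genes the scaled nt-RNA and p-RNA together came to less than 0.5 of tc-RNA. SGK1, TAF1D, SFXN3 and DNAJB9, named above as low in p-RNA, were among these genes. Noise of single arrays stays possible for part of the 104 genes, since 49 of the 104 fell short in each of the 3 replicate numbers. For those 49 it was argued against by a test added after that count was seen, in which 60.5% of 81 genes short in number 1 were also short in numbers 2 and 3 (exact 95% interval 49.0% to 71.2%), against 0.320% of the other genes. Probe sets with the suffix _x_at made up 27.9% of the 104 and 6.33% of the other genes (Fisher's exact test, two-sided, p = 1.21e-11), so that cross-hybridisation may underlie part of them. Together with the suffix _s_at the shares were 39.4% and 40.0%, and 63 of the 104 genes had neither suffix, so it was argued against as the whole cause. Loss of a class of RNA in the separation could not be tested, as 0 further fractions were measured, and no biological explanation was tested.

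Other splits of the arrays were compared with the real one. Each comparison has 10 splits of its 6 arrays, too few for a share under 0.05. The real split gave 4650, 394 and 5485 called genes for nt-RNA against tc-RNA, p-RNA against tc-RNA and nt-RNA against p-RNA, 1 split of 10 in each case, and the highest other split gave 0 by limma. At an unadjusted p under 0.05 the other splits reached 915, 1083 and 641 genes, against 5135, 1027 and 5792 for the real ones.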
